A study of Neurospora crassa with 11 samples.

How the data were processed

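Transcript levels were measured by RNA-seq in 11 libraries of Neurospora crassa mycelium. Per the labels' protocols, total RNA was extracted with phenol and chloroform, precipitated with ethanol, treated with DNase and cleaned on a column, and libraries followed standard Illumina protocols. Whether the protocol kept strand is not given in the sources used here, so reads of overlapping or antisense genes cannot be told apart. Per the submitters' processing notes, the tools used were TopHat2 2.04, HTSeq 0.6, Cufflinks 2.02 and Cuffdiff 2.02, and their settings and the genome build are not given in the sources used here. The loci in the deposited tables lie on contigs named as in assembly NC12. With starts counted from 0, 9750 of the 9757 loci matched to the RefSeq annotation had the RefSeq gene's length. Coordinates in the text are those of the deposited tables, counted from 1. Gene symbols came from RefSeq, in which 1118 loci had a symbol of their own, and the other genes keep their locus names. Product names came from the authors' comparison tables.

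The deposited count tables hold the authors' raw read counts for 9758 genes, 1 table per library. Each ends in 5 entries that name no gene, such as reads that overlap no gene or align to several places. These made up 6.34% to 29.57% of the entries' total and stayed out of library sizes and tests. The highest share was that of deletion library 2, where reads without a unique alignment made up 22.68%. The deposited FPKM tables give the authors' fragment counts scaled by transcript length and library size, 1 table per library, per the file headers. The authors' deposited comparison tables hold mean FPKM per group, a log2 fold change and an adjusted p-value for 9600 genes, per the file headers, and how the p-value was adjusted is not given in the sources used here. They set wild type without carbon against wild type on xylan and against A828V without carbon. Their means and calls are printed as the authors' values. The 12 columns of single libraries in these tables were not used.

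Groups and replicate numbers came from the labels. The labels do not say that libraries of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical. No pair of libraries agreed within sampling noise, the lowest chi-square per degree of freedom being 19.5. The groups, the tests, the gene lists, the rule for named genes and all alternatives but those named below as chosen later were fixed before the data were examined.

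Counts were tested with edgeR 4.0.16 in R 4.3.3, with TMM factors, the filterByExpr filter (count minimum of 10) and the quasi-likelihood F-test, 2-sided, with Benjamini-Hochberg adjustment over the 8557 genes tested and calls at an adjusted p under 0.05. All 11 libraries entered 1 fit with 1 coefficient per group, which left 7 residual degrees of freedom and gave a common biological coefficient of variation of 0.411. On log2 CPM, pairs of A828V libraries without carbon correlated at 0.986 to 0.993, wild-type pairs at 0.914 to 0.971 and deletion pairs at 0.88 to 0.944. Leaving out 1 of these A828V libraries can thus raise the shared spread and end calls whose folds hardly move, which was not tested. The comparisons were deletion against wild type on xylan, A828V without carbon against A828V on sucrose, and A828V without carbon against wild type on xylan. CPM values in the text use library sizes times TMM factors, as mean ± SD over libraries.

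Gene lists were tested with camera in limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, and Benjamini-Hochberg adjustment over the lists of a comparison. camera with an estimated correlation and fry stood beside it, and lists needed at least 3 tested members. With an estimated correlation no list passed in any comparison when all lists were tested with all their members. The lists were xylan degradation, cellulases and beta-glucosidases, lytic polysaccharide monooxygenases, pectin degradation, pentose catabolism and pentose phosphate pathway, sugar transporters, starch degradation, gluconeogenesis and glyoxylate cycle, glycolysis and fermentation, conidiation, light response and clock, endoplasmic reticulum folding, cell wall and carbon regulators, mating type A, engineered loci, cytosolic ribosomal proteins, aminoacyl-tRNA synthetases, proteasome, and heat shock proteins and chaperonins. From them 3 members were removed because their product name gave another function (NCU00988 and NCU06138, named for quinate transport, and NCU04410, a tRNA ligase), and 1 had no entry in the count tables. Besides xlr-1, his-3 and the mating type A genes, the rule named, per comparison, the 10 genes with the largest rise and the 10 with the largest fall among those called. These needed a mean of at least 10 CPM in the higher group and no overlap between the groups' libraries. It also named members of the lists, and for the authors' tables the 10 most raised and 5 most lowered genes with at least 10 FPKM in the higher group. Overlaps of calls were tested with Fisher's exact test (scipy 1.17.1, Python 3.11.15).

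Alternatives were DESeq2 1.42.0, RLE size factors, no filter on low counts, a stricter filter (10 CPM in 3 libraries), a fit of the 2 groups alone, calls at an adjusted p under 0.01 or with a 2-fold change, limma on log2(FPKM + 1) and log2(FPKM + 0.1), each with at least 1 FPKM in 3 libraries, the replicate number as a block, and leaving out each library in turn. The block fit held all libraries but that on sucrose, so the A828V libraries without carbon shared its block terms. A block fit of the wild-type and deletion libraries alone and a fit less both libraries numbered 1 were chosen after seeing the data. In both block fits deletion library 4 was alone in its block and added nothing to the contrast with wild type. A fold change on the log2(FPKM + 1) scale understates the change of low genes. Whether the replicate numbers pair libraries was checked by the correlation, over genes, of deviations from the group mean. It was 0.64, 0.26 and 0.25 for wild type and deletion libraries 1, 2 and 3, each above the minimum of 0.1, so these numbers were taken as pairing the libraries. Different numbers passed that minimum too, at 0.25 for wild-type library 3 with deletion library 2 and 0.16 for wild-type library 2 with deletion library 3. Deviations within a group cancel out, so the 2 libraries numbered 1 can make the others correlate, and numbers 2 and 3 are weakly backed. The pairing comes from the data, since the labels name no shared day or batch. For wild type and A828V it was -0.10, -0.23 and -0.17, so those numbers do not pair libraries.

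The fits were checked on simulated data in which 67, 67 and 66 genes were changed 2-, 4- and 8-fold. For deletion against wild type (8443 genes), edgeR recovered 14.9% of genes changed 2-fold, 70.1% of those changed 4-fold and 97% of those changed 8-fold, with 4 false calls among 8243 unchanged genes. For A828V without carbon against sucrose (8437 genes) it recovered 0%, 13.4% and 63.6%, with 3 false calls, and for A828V without carbon against wild type (8446 genes) 4.5%, 65.7% and 90.9%, with 3 false calls. DESeq2 made 31, 54 and 30 false calls in the same simulations.

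Gene counts per library ran from 10317390 to 18927605. Where a group had 0 counts of a gene, its fold is a lower bound against a floor of 3 counts over the group, and with 1 to 3 counts the ratio is given with an exact Poisson interval at 95%. Floors and intervals cover counting error only, since PCR copies are not independent molecules. The ChIP-seq data named in the series' design and the libraries of wild type without carbon were not used here.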

Results

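RNA from whole mycelium of the filamentous fungus Neurospora crassa was sequenced in 11 libraries that fall into 4 groups. Cultures had been grown for 16 h on sucrose in Vogel's minimal medium, a defined salt medium, then washed and moved to fresh medium with xylan, with sucrose or with no carbon source. Xylan is the main hemicellulose polymer of plant cell walls, built on a chain of xylose. The groups were wild type on xylan (3 libraries), a strain with the transcription factor gene xlr-1 deleted on xylan (4 libraries), a strain carrying the XLR-1 A828V allele without carbon (3 libraries), and the same A828V strain on sucrose (1 library). Per the labels, the allele stood at the his-3 locus behind the ccg-1 promoter, in a strain whose own xlr-1 had been deleted. Counts assigned to genes came to 10568613, 13519404 and 18927605 for the wild-type libraries 1 to 3, and to 10796239, 10317390, 13440248 and 12285988 for the deletion libraries 1 to 4. They came to 16998222, 18507550 and 13937020 for the A828V libraries without carbon and to 14119872 for the A828V library on sucrose. The study asked what XLR-1 and related regulators do in plant cell wall degradation.

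The deleted gene was looked at first. xlr-1 (NCU06971; chromosome IV, 4706112 to 4709560) stood at a normalised read count of 135 ± 22.8 CPM (counts scaled to library size; SD, n = 3) in wild type on xylan and at 7.62 ± 3.86 CPM (SD, n = 4) in the deletion strain, where each of the 4 libraries lay below each wild-type library. The log2 fold change was -4.15 (SE 0.39, adjusted p = 0.000342, edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). In the A828V strain xlr-1 stood at 109, 129 and 115 CPM in the 3 libraries without carbon and at 199 CPM in the library on sucrose. It did not pass the edgeR test between these media (log2 fold change -0.76, adjusted p = 0.326 after Benjamini-Hochberg adjustment) or between A828V without carbon and wild type on xylan (-0.20, adjusted p = 0.741). The insertion locus his-3 stood at 290 ± 101 CPM (SD, n = 3) in wild type on xylan and 170 ± 45.4 CPM (SD, n = 4) in the deletion strain. It stood at 97.6 ± 7.47 CPM (SD, n = 3) in the A828V strain without carbon and 412 CPM on sucrose. matA-1 (NCU01958; chromosome I, 1860692 to 1862194), a gene of mating type A, had 125, 93 and 91 counts in the wild-type libraries and 143, 130 and 107 in the A828V libraries without carbon. It had 12 counts in the sucrose library and 0 in each of the 4 deletion libraries, which made it at least 123-fold lower there than in wild type, against a floor of 3 counts over the group.

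**Figure D1:**
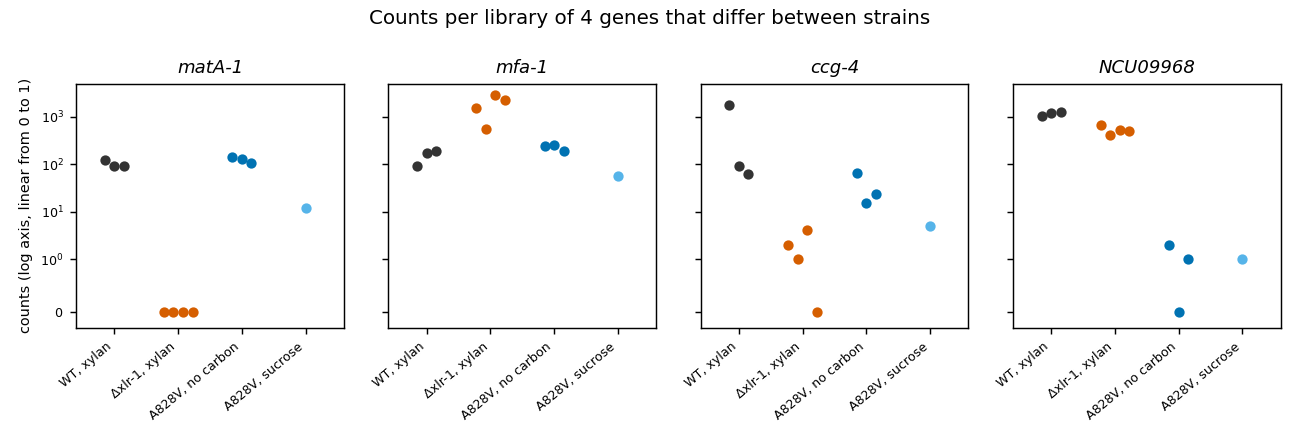
Counts in each library of matA-1, the pheromone genes mfa-1 and ccg-4, and NCU09968, 1 panel per gene and 1 point per library in each of the 4 groups, on a log axis that is linear from 0 to 1. The 4 deletion libraries had 0 counts of matA-1, and the 4 A828V libraries had at most 2 counts of NCU09968.

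The first comparison asked which genes differed between the strain without xlr-1 and wild type on xylan. Direct effects of the deletion, indirect ones and other differences between the strains cannot be told apart in it. Without xlr-1, 10 of 19 xylan degradation genes and 3 of 9 genes of pentose catabolism and the pentose phosphate pathway were lower than in wild type. The xylanase gene gh10-2 (NCU08189; chromosome III, 4598536 to 4599913) fell from 8232 ± 2805 CPM (SD, n = 3) in wild type to 20.5 ± 4.51 CPM (SD, n = 4), a 401-fold difference. The gene of xylose reductase, xr (NCU08384), the first enzyme of xylose catabolism, fell from 12180 ± 4618 to 149 ± 45.6 CPM, and that of the sugar transporter cdt-2 (NCU08114) from 3733 ± 862 to 65.7 ± 40.4 CPM (SD, n = 3 and 4). The pheromone precursor gene mfa-1 (NCU16992) rose from 11.2 ± 1.95 to 150 ± 80.8 CPM (SD, n = 3 and 4). That rise cannot be told apart from a difference in mating type between the strains.

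**Figure D2:**
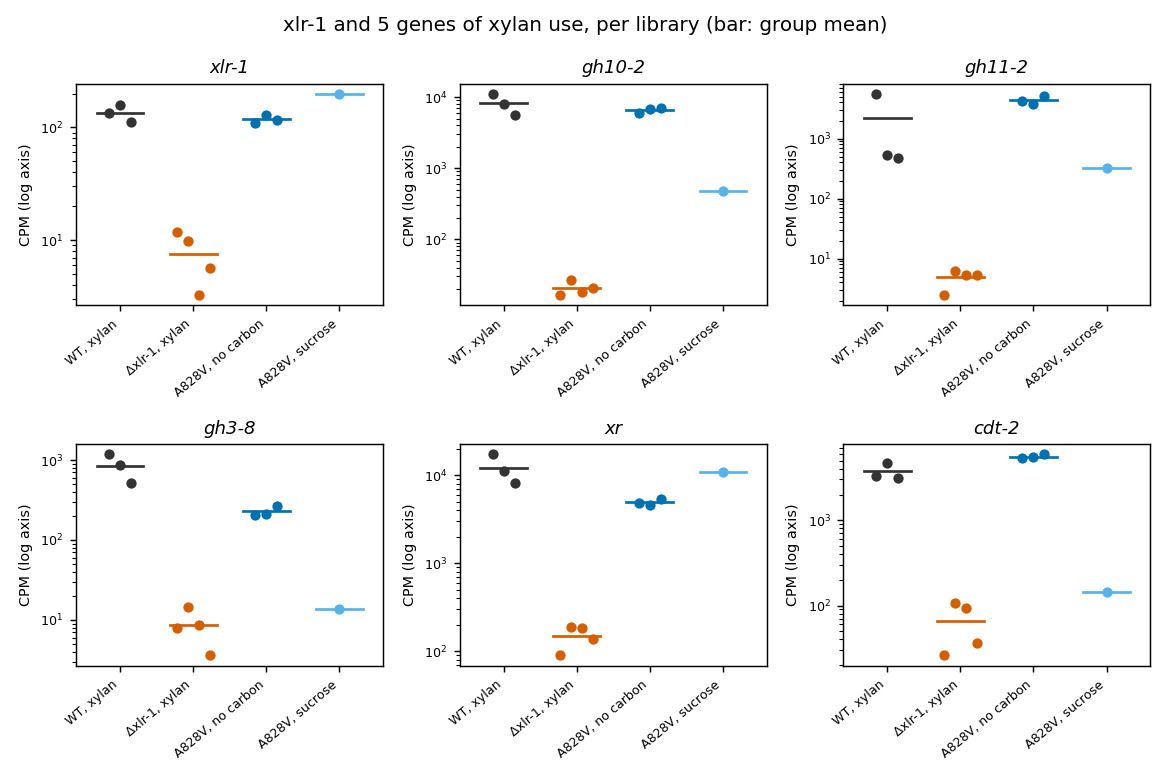
CPM on a log axis for xlr-1 and 5 genes of xylan use, 1 panel per gene, with 1 point per library and a bar at the mean of each group. In each panel the 4 deletion libraries lie below the 3 wild-type libraries, and gh10-2 averaged 8232 CPM in wild type on xylan and 6612 CPM in the A828V strain without carbon.

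Of the 19 tested members of the xylan degradation list, 10 fell, 0 rose and 9 were not called in the deletion strain, and adjusted over the list alone 13 fell. The log2 fold change was -8.65 (SE 0.39) for gh10-2 and -8.83 (SE 0.99) for the xylanase gene gh11-2, which stood at 5610, 535 and 478 CPM in the wild-type libraries and changed by -6.70 without wild-type library 1. It was -6.63 (SE 0.50) for the beta-xylosidase gene gh3-8 and -3.79 (SE 0.38) for NCU02343, an alpha-L-arabinofuranosidase gene. Their adjusted p-values from the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment were 4.42e-06, 0.00121, 6.61e-05 and 0.00052. As a set, the list was lower than other genes (camera with Benjamini-Hochberg adjustment over the lists, adjusted p = 2.17e-23), and with an estimated correlation the adjusted p was 0.0519. The xylanase gene gh10-1 was not called (log2 fold change -8.86, edgeR Benjamini-Hochberg adjusted p = 0.0718), with 4124, 53 and 96 counts in the wild-type libraries. It was called without wild-type library 2 (-9.51) or 3 (-9.49). It was also called in 2 fits chosen after seeing the data, that with the replicate number as a block on wild-type and deletion libraries alone (-8.31, adjusted p = 0.00122) and that less both libraries numbered 1 (-7.05, adjusted p = 0.00226). The alpha-glucuronidase gene NCU07351 stood at 322 ± 202 CPM in wild type and 338 ± 368 CPM in the deletion strain (SD, n = 3 and 4).

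Of the 9 members of the list of pentose catabolism and the pentose phosphate pathway, 3 fell and 6 were not called by edgeR, and adjusted over the list alone 7 fell, while DESeq2 called 6 lower and limma on FPKM called 4. Those called by edgeR over all genes were xr (log2 fold change -6.35, SE 0.42), the xylitol dehydrogenase gene NCU00891 (-3.82, SE 0.34) and the xylulose kinase gene xyk-1 (-4.26, SE 0.41), the 3 steps from xylose to xylulose 5-phosphate. The camera test gave an adjusted p of 1.61e-11 for the list, and the adjusted p was 0.0519 with an estimated correlation. Of the 16 tested sugar transporters, 1 fell (cdt-2, -5.83, SE 0.53), 0 rose and 15 were not called by edgeR, and adjusted over the list alone 2 fell, as with DESeq2 over all genes. The median log2 change of the transporters was 0.08 and the mean -0.34, so the signs differed, and camera gave an adjusted p of 0.385. fry, which tests whether the genes of a list move on balance one way and does not compare them with other genes, gave an adjusted p of 0.0152 toward lower values. Among the 8 regulators of cell wall and carbon genes, edgeR called xlr-1 alone and DESeq2 1 lower and 1 higher, and adjusted over the list alone 3 were lower and 1 was higher. The largest falls outside the lists included the putative quinate permease gene NCU06138 (-7.77, SE 0.43) and NCU00292, annotated as a cholinesterase (-8.34, SE 0.44). NCU07224, the gene next to gh11-2, had 1 count over the 4 deletion libraries, a ratio of wild type to deletion of 832 with a 95% counting interval of 149 to 32800. It had 490, 96 and 111 counts in the wild-type libraries, and without wild-type library 1 the ratio was 331 (59.3 to 13100). limma on FPKM did not call it (log2 change -2.82, adjusted p = 0.0725).

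The members of 13 further lists, 223 in all, held 0 edgeR calls in this comparison, while 47 had an unadjusted p under 0.05, DESeq2 called 4 and limma on FPKM called 0. They included the 10 tested cellulases and beta-glucosidases, 14 lytic polysaccharide monooxygenases (oxidative cellulose-cleaving enzymes) and 7 pectin degradation genes. The cellobiohydrolase gene cbh-1 stood at 58.7 ± 45.8 CPM in wild type and 47.7 ± 8.72 CPM in the deletion strain (SD, n = 3 and 4). For the 73 cytosolic ribosomal proteins the camera adjusted p was 4.78e-15 toward lower values, and 0.302 with an estimated correlation. For the 33 aminoacyl-tRNA synthetases it was 0.000738, also lower, and 0.396 with an estimated correlation. For pectin degradation it was 0.0477 (lower), for conidiation 0.0491 (higher) and for the proteasome 0.0228 (higher). With an estimated correlation these adjusted p-values were 0.252, 0.302 and 0.573. The camera adjusted p was 0.83 for cellulases, 0.389 for the monooxygenases, 0.891 for starch degradation and 0.384 for gluconeogenesis and the glyoxylate cycle. It was 0.0805 for glycolysis and fermentation, 0.0799 for light response and clock, 0.0609 for endoplasmic reticulum folding and 0.0519 for heat shock proteins. It was 0.0805 for the regulators and 0.0723 for the 3 engineered loci, which share xlr-1. The median log2 change of starch degradation was 0.02, the mean -0.07 and the test direction lower. Adjusted over the list alone, 1 cellulase gene and 1 pectin gene were lower and 0 members of the other 11 lists were called. Of the engineered loci, 2 were lower and 1 was higher when adjusted over the list alone, and matA-1 was the 1 tested gene of mating type A. The pectin call was lost without wild-type library 1 (0.0671) or 2 (0.145) or deletion library 1 (0.129) or 4 (0.0651). That of conidiation was lost without wild-type library 1 (0.144) or deletion library 1 (0.125) or 2 (0.164), and that of the proteasome without wild-type library 2 (0.145) or 3 (0.172) or deletion library 1 (0.356). With the replicate number as a block, glycolysis and fermentation (camera adjusted p = 0.00447) and heat shock proteins (0.00139) passed toward lower values. In the block fit of wild-type and deletion libraries alone they passed too (0.000626 and 0.000232), as did endoplasmic reticulum folding (0.0463). Without a block the 2 former lists failed with an estimated correlation (adjusted p = 0.573 for each) and by fry (0.435 and 0.368). By fry ribosomal proteins (adjusted p = 0.0978), aminoacyl-tRNA synthetases (0.161), conidiation (0.161) and the proteasome (0.368) did not pass. The regulators (0.0314) and the engineered loci (0.00214) passed by fry toward lower values with xlr-1, whose fall the deletion fixed, among them. In lists without xlr-1, a choice made after seeing the data, the regulators did not pass (fry adjusted p = 0.591, camera 0.552), and the engineered loci, then 2 genes, were not tested. Over the 17 lists left, the adjusted p with an estimated correlation was 0.049 for xylan degradation and 0.049 for pentose catabolism. For heat shock proteins camera with the preset correlation gave 0.049, while the adjusted p was 0.631 with an estimated correlation and 0.411 by fry.

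Several lists that did not pass camera with all libraries passed it in fits less 1 library. Glycolysis and fermentation was lower without wild-type library 1 (adjusted p = 0.0316) or 2 (0.0432) or deletion library 4 (0.00761). Heat shock proteins were lower without wild-type library 1 (0.0391) or 2 (0.023) or deletion library 3 (0.0162) or 4 (0.00303), endoplasmic reticulum folding without wild-type library 2 (0.0432) or 3 (0.0275), and the engineered loci without wild-type library 1 (0.033). Light response and clock was higher without wild-type library 1 (0.0051) or deletion library 2 (0.0142), and less both libraries numbered 1 (0.0231). That last fit, chosen after seeing the data, lost the camera calls of pectin degradation (0.0853), conidiation (0.131) and the proteasome (0.057). Cellulases were lower without wild-type library 3 (0.0492) and higher without wild-type library 1 (0.0217).

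In all, 2 genes were higher and 49 lower in the deletion strain among 8557 tested (edgeR, Benjamini-Hochberg adjusted p under 0.05), and 1221 had an unadjusted p under 0.05. The higher genes were mfa-1 (log2 fold change 3.74, SE 0.49, edgeR Benjamini-Hochberg adjusted p = 0.00396) and pre-2 (NCU05758), a pheromone receptor gene chosen after its values were seen (2.36, SE 0.44, adjusted p = 0.0481). Since the deletion libraries had 0 counts of matA-1, these rises and the fall of ccg-4 cannot be told apart from a difference in mating type. The lower genes included the pheromone gene ccg-4 (-8.69, SE 1.55, edgeR Benjamini-Hochberg adjusted p = 0.0383), which had 1813, 93 and 63 counts in the wild-type libraries. Its log2 fold change was -5.16 without wild-type library 1, -9.28 without 2, -9.30 without 3 and -9.37 without deletion library 3. In A828V without carbon, where matA-1 was read, ccg-4 was also lower than in wild type on xylan (-5.12, edgeR Benjamini-Hochberg adjusted p = 0.0285). That call was lost without wild-type library 1 (-1.58), without any 1 A828V library and with limma on FPKM. The authors' deposited table had it lower too, with both strains without carbon (-7.05). The wild-type and deletion libraries with the same number deviated together, and with the replicate number as a block 6 genes were higher and 38 lower, pre-2 and ccg-4 not among them. limma on FPKM, where the median gene shifted by 0.11 on the log2 scale, gave 17 higher and 51 lower, or 25% higher against 3.92% in the edgeR fit, and did not call pre-2 (adjusted p = 0.0587) or ccg-4 (0.126). DESeq2 gave 168 higher and 222 lower, or 43.1% higher, and an edgeR fit of the 2 groups alone gave 1 and 31. In 2 fits chosen after seeing the data, the block on these 7 libraries alone gave 12 and 85 and the fit less both libraries numbered 1 gave 4 and 56. pre-2 was called in neither, and ccg-4 not in the latter. The calls of 31 lower genes and of mfa-1 were kept in every fit that left out 1 library. The acetyl xylan esterase gene NCU00710 lost its call without wild-type library 1 or 2 or deletion library 1, 2 or 3 and less both libraries numbered 1, ccg-4 without any 1 deletion library, and pre-2 without any 1 library other than deletion library 2. The number of higher genes reached 13 without deletion library 1.

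The A828V strain was compared without carbon and on sucrose, the carbon source that represses many of these genes. Without carbon, 4 of 19 xylan degradation genes, 8 of 16 sugar transporters and 4 of 7 conidiation genes were higher than in the 1 library on sucrose. Lower without carbon were 65 of 73 ribosomal protein genes and 7 of 12 genes of glycolysis and fermentation, and none of these lists passed with an estimated correlation. gh10-2 stood at 6612 ± 495 CPM (SD, n = 3) without carbon and 484 CPM in the sucrose library, a log2 fold change of 3.77 (SE 0.58, edgeR Benjamini-Hochberg adjusted p = 0.00392). cdt-2 stood at 5547 ± 314 CPM (SD, n = 3) and 144 CPM (5.27, SE 0.98), and the conidiation gene con-6 at 1185 ± 159 CPM (SD, n = 3) and 2.29 CPM (9.01, SE 1.41). The fatty acid synthase gene cel-1 stood at 5.64 ± 0.92 CPM (SD, n = 3) without carbon and 604 CPM on sucrose (-6.74, SE 0.70).

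In the xylan degradation list 4 of 19 genes rose, 1 fell and 14 were not called by edgeR, and adjusted over the list alone 8 rose and 1 fell. The risers were gh10-2, gh3-8 (log2 fold change 4.05, SE 0.82), the acetylxylan esterase gene NCU05159 (4.84, SE 1.03) and the feruloyl esterase gene NCU09491, with 594, 811 and 819 counts without carbon and 7 on sucrose. The alpha-glucuronidase gene NCU07351 was lower (-4.23, SE 1.31, edgeR Benjamini-Hochberg adjusted p = 0.0475), a call lost without any 1 of the libraries without carbon and with limma on FPKM (adjusted p = 0.084). DESeq2 called 9 genes of the list higher and 1 lower, and limma on FPKM called 8. camera gave an adjusted p of 0.000415 for the list, and the adjusted p was 0.47 with an estimated correlation. Of the 9 genes of pentose catabolism and the pentose phosphate pathway edgeR called 0, with 2 at an unadjusted p under 0.05, 1 called by DESeq2 and 2 by limma on FPKM. xr stood at 10830 CPM in the sucrose library and 4951 ± 376 CPM (SD, n = 3) without carbon.

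Of the 16 sugar transporters, 8 rose and 0 fell, and adjusted over the list alone 8 rose. Besides cdt-2 they included NCU02188 (log2 fold change 5.53, SE 0.67), NCU01132 (5.30, SE 0.65) and NCU09287 (6.19, SE 0.64). NCU08152, annotated as a high affinity glucose transporter, had 3 counts on sucrose, a ratio of 401 with a 95% counting interval of 137 to 1950. The call of NCU01494 was lost without any 1 of the libraries without carbon. The camera adjusted p for the transporters was 0.000136, and 0.0525 with an estimated correlation. Of 7 conidiation genes 4 rose, among them con-6 and con-8 (4.32, SE 0.75), and adjusted over the list alone 6 rose (camera adjusted p = 0.000136, and adjusted p = 0.183 with an estimated correlation). The con-10 call was lost without library 1 or 3 of those without carbon. Among the 8 regulators clr-1 (2.15, SE 0.47) and NCU05414 (5.47, SE 0.47) rose and the carbon catabolite repressor gene cre-1 fell (-3.02, SE 0.73). The cre-1 call was lost without library 1 or 3 of those without carbon. Adjusted over the list alone, 3 regulators rose and 1 fell (camera adjusted p = 0.281, and 0.00216 by fry toward higher values).

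Of 73 cytosolic ribosomal proteins 65 fell, 1 rose and 7 were not called, and adjusted over the list alone 69 fell and 1 rose (camera adjusted p = 1.28e-30, and adjusted p = 0.26 with an estimated correlation). Of 33 aminoacyl-tRNA synthetases 14 fell and 0 rose, and adjusted over the list alone 20 fell (camera adjusted p = 1.29e-05, and adjusted p = 0.455 with an estimated correlation). DESeq2 called 18 of the synthetases lower and limma on FPKM called 5. Of 12 genes of glycolysis and fermentation 7 fell and 0 rose. The falls included the enolase gene emp-7 (log2 fold change -2.95, SE 0.60) and the triosephosphate isomerase gene NCU07550 (-2.18, SE 0.40), which limma on FPKM did not call. The calls of gpd-1 and cfp were lost without any 1 of the libraries without carbon, and that of pgk without library 1 or 3. Adjusted over the list alone all 12 fell (camera adjusted p = 1.29e-05, and adjusted p = 0.358 with an estimated correlation), while DESeq2 called 11 lower and limma on FPKM called 4. Further large falls were those of am, the glutamate dehydrogenase gene (-7.22, SE 1.26), cel-2 (-5.94, SE 0.72) and the pyridoxine gene pdx-1 (-5.94, SE 0.89). Among the largest rises was NCU09184, annotated as an indoleamine 2,3-dioxygenase (9.31, SE 1.85).

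**Figure D3:**
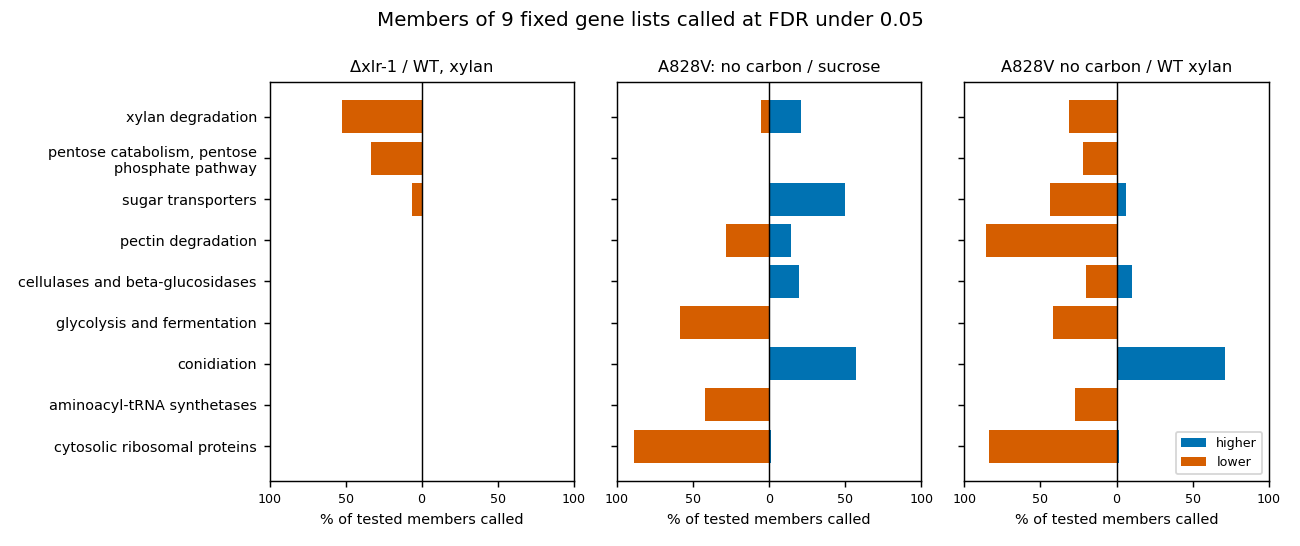
Percentage of the tested members of 9 gene lists that were called higher (right of 0) or lower (left of 0) at an adjusted p under 0.05 in each of the 3 comparisons, by the edgeR quasi-likelihood test. Of the 19 xylan degradation genes 10 were lower in the deletion strain, and of the 73 ribosomal proteins 65 were lower without carbon than on sucrose in the A828V strain.

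In all, edgeR called 718 genes higher and 894 lower without carbon, or 44.5% higher. limma on FPKM, where the median gene shifted by 0.45 on the log2 scale against 0.11 in the edgeR fit, gave 1397 higher and 428 lower, or 76.5% higher. DESeq2 gave 1200 and 1153, and an edgeR fit of the 2 groups alone 2676 and 2590. The sucrose group held 1 library, which was assumed to vary like the other groups, so the difference between media has no check by replicates on that side. The calls of 292 higher and 398 lower genes were kept whichever 1 of the libraries without carbon was left out, and the counts fell to 304 higher without library 3 and 409 lower without library 1.

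The last comparison between libraries set the A828V strain without carbon against wild type on xylan, so that strain and medium both differed. The xylanase gene gh10-2 did not pass the test, while 6 of 7 pectin degradation genes and 7 of 16 transporters were lower in the A828V strain and 5 of 7 conidiation genes were higher. gh10-2 stood at 6612 ± 495 CPM in the A828V strain without carbon and 8232 ± 2805 CPM in wild type on xylan (SD, n = 3 and 3; log2 fold change -0.32, SE 0.32, edgeR Benjamini-Hochberg adjusted p = 0.508). cdt-2 stood at 5547 ± 314 and 3733 ± 862 CPM (0.57, SE 0.49, adjusted p = 0.429), and gh11-2 at 4428 ± 699 and 2207 ± 2947 CPM (SE 0.81 on the log2 scale, adjusted p = 0.396). gh11-2 was called higher without wild-type library 1 (3.13) and by limma on FPKM (2.42, adjusted p = 0.0358). The L-arabinitol dehydrogenase gene NCU00643 fell from 1352 ± 529 to 36.2 ± 6.80 CPM (-5.22, SE 0.41, edgeR Benjamini-Hochberg adjusted p = 0.00013).

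Of the 19 xylan degradation genes 6 were lower, 0 higher and 13 not called, and adjusted over the list alone 7 were lower and 1 higher (camera adjusted p = 0.152). Among the 6, gh3-8 stood at 229 ± 34.2 and 851 ± 333 CPM (SD, n = 3 and 3; log2 fold change -1.89, SE 0.46), a call lost without wild-type library 1 or any 1 A828V library. Without A828V libraries 1, 2 and 3 its log2 fold change was -1.82, -1.85 and -2.02. The calls of NCU04870, NCU09664, NCU09775, NCU07351 and NCU00710 were likewise lost without any 1 A828V library. Leaving out a wild-type library also ended that of NCU04870 (library 1, log2 fold change -0.69), NCU09664 (1, -1.65), NCU07351 (2 or 3, -3.54 and -3.59) and NCU00710 (1 or 2, -1.75 and -1.94), and the block that of NCU04870 (-2.18). limma on FPKM did not call NCU04870 (adjusted p = 0.191), NCU09664 (0.0904), NCU07351 (0.0516) or NCU00710 (0.0556). In the pentose list edgeR called xr (-1.30, SE 0.38) and NCU00643 lower and 7 genes not, also when adjusted over the list alone (camera adjusted p = 0.00762, and adjusted p = 0.324 with an estimated correlation). The xr call was lost without wild-type library 1 or 2 or any 1 A828V library, and also with the replicate number as a block or with limma on FPKM (adjusted p = 0.129), which called 1 gene of the list.

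Of 7 pectin degradation genes 6 fell, and adjusted over the list alone all 7 did (camera adjusted p = 8.21e-05, and adjusted p = 0.0557 with an estimated correlation). They included the exopolygalacturonase gene gh28-2 (log2 fold change -3.44, SE 0.34), NCU02654 (-2.48, SE 0.47) and asd-1 (-2.23, SE 0.36). The calls of gh28-1, NCU06326 and NCU08176 were lost without any 1 A828V library, and also without wild-type library 2 (gh28-1, -1.78, and NCU06326, -2.26), 3 (gh28-1, -1.92) or 1 (NCU08176, -2.01). limma on FPKM did not call gh28-1 (adjusted p = 0.0898) or NCU08176 (0.0655). The neighbouring genes NCU09532 and NCU09533, the former annotated as an aldolase for L-threo-3-deoxy-hexulosonate, a compound of galacturonate catabolism, were among the largest falls (-5.68, SE 0.35, and -6.68, SE 0.52). Of 16 transporters 7 fell and 1 rose, and adjusted over the list alone 7 fell and 2 rose. The camera adjusted p was 0.00937, and the adjusted p was 0.114 with an estimated correlation. The calls of hgt-1 and NCU05627 were lost without A828V library 1 or 3. NCU05897 fell from 5297 ± 825 to 258 ± 38.2 CPM and NCU04963 from 3967 ± 1767 to 348 ± 25.7 CPM, while NCU08152 rose from 2.53 ± 2.59 to 108 ± 22.1 CPM (SD, n = 3 and 3), by 5.39 on the log2 scale and 6.50 without wild-type library 2.

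Of 7 conidiation genes 5 rose, and adjusted over the list alone all 7 did. The camera adjusted p was 3.03e-05, and the adjusted p was 0.108 with an estimated correlation. The eas call was lost without wild-type library 2 or any 1 A828V library, and that of ccg-1 without A828V library 3. con-6 stood at 1185 ± 159 CPM against 5.12 ± 1.77 CPM in wild type on xylan (SD, n = 3 and 3; log2 fold change 7.86, SE 0.79), and the conidiation regulator fl at 128 ± 34.9 against 28.0 ± 7.63 CPM (2.19, SE 0.33). Of 73 ribosomal proteins 61 fell and 1 rose, and adjusted over the list alone 68 fell and 1 rose (camera adjusted p = 4.39e-23, and adjusted p = 0.269 with an estimated correlation). NCU09968 (chromosome VI, 309546 to 315476), a gene of unknown function, had 1018, 1195 and 1242 counts in wild type and 2, 0 and 1 in the A828V libraries without carbon. The ratio was 1660 with a 95% counting interval of 567 to 8030. The overlapping gene NCU09969, chosen after its values were seen, had 104, 64 and 152 counts in wild type and 0 in each A828V library, at least 153-fold lower without carbon against a floor of 3 counts over the group.

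In all, edgeR called 795 genes higher and 983 lower in the A828V strain without carbon than in wild type on xylan, or 44.7% higher. limma on FPKM, where the median gene shifted by 0.30 on the log2 scale, gave 1527 higher and 522 lower, or 74.5% higher. DESeq2 gave 1235 and 1369, and an edgeR fit of the 2 groups alone 1489 and 1524. The calls of 245 higher and 251 lower genes were kept in every fit that left out 1 library, and the counts fell to 266 higher and 274 lower without A828V library 3. They fell to 274 and 276 without A828V library 1 and to 332 and 444 without A828V library 2, and with wild-type libraries 1, 2 or 3 left out the higher genes numbered 424, 531 and 414.

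Wild type without carbon entered only through the authors' deposited tables of means and calls, and those libraries were not analysed here. In the authors' deposited table of wild type on xylan against wild type without carbon, 526 genes were higher and 172 lower on xylan. In the authors' deposited table of A828V against wild type, both without carbon, 262 genes were higher and 140 lower in the A828V strain. xr had an authors' mean of 8.57 FPKM without carbon and 5434 on xylan in the first authors' deposited table, a log2 change of 9.31, and 9.86 and 2666 FPKM in wild type and A828V in the second authors' deposited table, a log2 change of 8.08. gh10-2 had log2 changes of 7.26 and 6.96 in the 2 authors' deposited tables. The tables were scaled separately, so levels are compared only within each. xlr-1 itself was not called in either of the authors' deposited tables (-0.03 and -0.36).

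Of 19 xylan degradation genes, 15 were higher on xylan than without carbon and 14 were higher in A828V than in wild type without carbon, according to the authors' deposited tables. Of the pentose list 4 and 3 of 9 genes were higher in the authors' deposited tables, of pectin degradation 5 and 1 of 7, of the transporters 8 and 4 of 15, and of ribosomal proteins 49 and 1 of 73. NCU00643 was higher on xylan (log2 change 5.17) and not called in A828V (0.03) in the authors' deposited tables. The authors' deposited table of A828V had clr-1 (1.33) and vib-1 (1.47) higher and acu-3 (-1.92), acu-5 (-1.84), ccg-4 (-7.05), am (-4.46) and NCU09968 (-10.07) lower. On xylan, con-6 (-6.26) and NCU09184 (-8.08) were lower in the authors' deposited table. Whether lists differ between the tables was not tested.

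Genes lower without xlr-1 on xylan were set against the other comparisons. Of the 49 such genes, 15, matA-1 among them, were higher in the A828V strain without carbon than on sucrose, against 4.11 for independent lists (odds ratio 4.90, two-sided Fisher's exact test, p = 6.54e-06). With DESeq2 calls in both comparisons 42 of 222 genes were shared against 31.8, which did not pass the test (odds ratio 1.41, Fisher's exact p = 0.0522). Of the 48 genes also in the authors' deposited table of A828V, 29 were higher in A828V without carbon, against 1.47 for independent lists (odds ratio 54.5, Fisher's exact p = 1.65e-32), and these comparisons share no library. Of 48 in the authors' deposited table of wild type, 36 were higher on xylan, against 2.98 for independent lists. Those 2 comparisons share the wild-type libraries on xylan. In 50 simulations with no effect, the top genes by p-value, in lists of the same size, shared 21.9 on average and 29 at most. Almost none of those genes were called, so they do not measure the overlap of called genes. Genes called in these simulations shared 0, but only 0.1 were called on average over both comparisons, so that count could hardly differ from 0. Part of the excess may come from the shared libraries, which are too few to split. Of the 48 genes tested in both of the authors' deposited tables, 29 were higher in both and 12 in neither, and NCU01906, chosen after its values were seen, was not compared. The authors' deposited tables shared 86 higher genes, against 15.3 for independent lists. In 50 simulations with a shared wild-type group and no effect, the top genes by p-value, in lists of the same size, shared 115 on average. The simulations used edgeR and the wild-type means on xylan in place of those without carbon, and called only 0.14 genes on average. Their lists thus differ from lists of called genes, so how much of the 86 came from the shared libraries cannot be told.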

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

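All tests in this part that weigh an explanation were chosen after the results they bear on had been seen. Among 45 quantities of the 4 deletion libraries, 8 had 1 library set far apart from the other 3, where chance would set apart about 2.2. For 2 of the 8, at 0 in 3 libraries, any count in the other library would set it apart. Among the other 43 quantities 6 had a library set apart, against about 2.1 under the same assumptions. In deletion library 1, gh10-1 stood at 1.05 CPM against at most 0.0907 in the others, gh11-1 at 5.64 against 3.08 to 3.30, NCU04537 at 15.8 against 1.81 to 2.39, hgt-1 at 12850 against 2890 to 3479, and gh6-3 at 53.3 against 14.2 to 16.7 CPM. In deletion library 2, NCU07224 stood at 0.0907 CPM, from 1 count, and NCU07510 at 0.453 CPM, from 5 counts, with 0 in the others. In deletion library 4, NCU09491 stood at 1.75 CPM against 4.43 to 4.99.

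Wild-type and deletion libraries with the same number deviated together from their group means, with same-number correlations of 0.25 or more. A day or batch shared by libraries with the same number is a candidate explanation: the lowest of the 3 correlations was 0.25, and each wild-type library was closest to the deletion library of its own number, though wild-type library 3 correlated at 0.25 with deletion library 2 as well after rounding. Deviations within a group cancel out, so the correlation of 0.64 between the libraries numbered 1 can by itself make the others correlate. Depth cannot be told apart from it, since the correlation of -0.35 between the shallowest wild-type and the shallowest deletion library rests on 1 pair and 2 of the 3 wild-type libraries were closest to the deletion library nearest in depth. The 51 calls between deletion and wild type exceeded those of the other 34 splits of the 7 libraries into 4 and 3. Of the 35 splits 1, the real one, gave as many, and the highest other gave 11. That share holds only if all libraries can swap freely, while the numbers were taken as pairing them. A real difference also widens the spread in the other splits and so lowers their calls, so chance was not excluded. Of the 8 splits that part all 3 pairs, which are too few for a share under 0.05, the real one gave 51 calls and the other 7 gave 0.

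The calls between deletion and wild type held the mating-type gene matA-1 and the pheromone gene ccg-4, both lower in the deletion strain. They also held the pheromone gene mfa-1 and the pheromone receptor gene pre-2, both higher there. The other mating type in the deletion strain is a candidate explanation: 0 reads of matA-1 were found over the 4 deletion libraries, while the genes on both sides of the mating-type locus had at least 19 reads in each. Loss of xlr-1 itself cannot be told apart from the strain's mating type with these libraries, since 19 reads beside the locus say only that the region was covered, the labels give the deletion strain no mating type, and no libraries of a deletion strain labelled mating type A were analysed here. The A828V strain is labelled mating type a, which alone would leave no matA-1 reads, yet its libraries without carbon held at least 107. On the same medium, without carbon, the authors' deposited table had matA-1 lower in A828V than in wild type (log2 change -2.36). Against wild type on xylan it was not called (-0.32).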

How the results depend on the processing

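The fits less both libraries numbered 1 and with the block on wild-type and deletion libraries alone, and the lists less xlr-1, were chosen after seeing the data; the other alternatives were set before. Between deletion and wild type, 2 genes were higher and 49 lower. Genes higher were 1 at an adjusted p under 0.01, 168 with DESeq2, 1 with no filter, 1 in a fit of the 2 groups, 17 and 20 with limma on log2(FPKM + 1) and log2(FPKM + 0.1), and 1 to 13 with 1 library left out. Genes lower were 31 at 0.01, 222 with DESeq2, 31 in the fit of the 2 groups and 39 to 57 with 1 library left out. With the replicate number as a block, in a fit that also held the A828V libraries without carbon, 6 were higher and 38 lower. A block fit of the 7 deletion and wild-type libraries alone gave 12 and 85, and the fit less both libraries numbered 1 gave 4 and 56. For A828V without carbon against sucrose (718 and 894), genes higher were 157 at 0.01, 1200 with DESeq2, 2676 in the fit of the 2 groups, 1397 and 1332 with limma, and 304 to 387 with 1 library left out; genes lower were 329, 2590 in the fit of the 2 groups, 428 and 401 with limma, and 409 to 541. For A828V without carbon against wild type (795 and 983), genes higher were 196 at 0.01, 1235 with DESeq2, 1489 in the fit of the 2 groups, 1527 and 1354 with limma, and 266 to 531; genes lower were 277, 1524, 522 and 503, and 274 to 991. There the numbers do not pair the libraries, and a block gave 1066 higher and 1244 lower. The overlap of genes lower in the deletion with those higher off sucrose was 42 genes with DESeq2 (Fisher's exact test, p = 0.0522). The list of cellulases turned from lower (camera adjusted p = 0.83) to higher without wild-type library 1 (0.0217) and was lower without wild-type library 3 (0.0492), in a range of 0.0217 to 0.97 with 1 library left out. The stricter threshold lowers counts by construction; for the rest the cause was not tested. RLE factors and a 2-fold minimum kept every count within 1.5 times. No named gene that was called turned direction. Depths of 10317390 to 18927605 counts per library limit folds of genes at 0 to 3 counts to bounds or intervals.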

Other observations

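The tests of explanations in this part were chosen after the results had been seen. Further gene lists were tested in the A828V strain, and none passed with an estimated correlation. Without carbon against sucrose, 2 of 10 cellulases and beta-glucosidases rose (camera adjusted p = 0.0162, and adjusted p = 0.593 with an estimated correlation). They were the beta-glucosidase genes gh3-4 (log2 fold change 7.28, SE 1.07) and gh3-3. The gh3-3 call was lost without any 1 of the libraries without carbon. Adjusted over the list alone 4 rose, with 4 called by DESeq2 and 5 by limma. Of 14 lytic polysaccharide monooxygenases 1 rose and 2 fell (camera adjusted p = 0.805), or 1 and 3 adjusted over the list alone and 2 and 3 with DESeq2, and of 7 pectin genes gh28-2 rose (3.74, SE 0.57) while gh28-1 (-3.96, SE 0.72) and asd-1 (-3.79, SE 0.44) fell (camera adjusted p = 0.805), or 2 and 2 adjusted over the list alone. The acetyl-CoA synthetase gene acu-5 fell (-4.37, SE 0.64), the only edgeR call among 5 genes of gluconeogenesis and the glyoxylate cycle (camera adjusted p = 0.896), with 1 higher and 1 lower adjusted over the list alone and by DESeq2, and 2 called by limma. Of 7 starch genes edgeR called 0, with 3 at an unadjusted p under 0.05 and 2 called by DESeq2 and 2 by limma, and adjusted over the list alone 0 were called (camera adjusted p = 0.896). The starch list had a median log2 change of -0.85, a mean of 0.12 and a test direction of higher. The carotenoid gene al-3 rose (2.92, SE 0.43), the only edgeR call among 8 light and clock genes (camera adjusted p = 0.28), also when adjusted over the list alone, while DESeq2 called 2 higher and limma called 3. Of 4 genes of endoplasmic reticulum folding 1 fell (camera adjusted p = 0.354), of 29 proteasome genes 1 fell (camera adjusted p = 0.000252, and adjusted p = 0.593 with an estimated correlation), and of 14 heat shock genes 4 fell (camera adjusted p = 0.0145, and adjusted p = 0.593 with an estimated correlation). By fry the cellulases (adjusted p = 0.0792), proteasome (0.0644) and heat shock genes (0.126) did not pass. Adjusted over the list alone 1 folding gene, 0 proteasome genes and 4 heat shock genes were lower, and of the proteasome DESeq2 called 7 lower and limma 0. Of the 3 engineered loci ccg-1 rose (4.50, SE 0.78) and his-3 fell (-2.08, SE 0.40; not called by limma on FPKM), also adjusted over the list alone (camera adjusted p = 0.896). Their median was -0.76, the mean 0.56 and the test direction lower. matA-1, the only tested gene of mating type A, was higher (2.66, SE 0.72, edgeR Benjamini-Hochberg adjusted p = 0.0422), with 12 counts in the sucrose library.

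Against wild type on xylan, A828V without carbon had 1 higher and 2 lower of 10 cellulases and beta-glucosidases (camera adjusted p = 0.965), the same numbers adjusted over the list alone, with gh3-4 higher (log2 fold change 4.29, SE 0.54) and gh1-1 lower (-1.75, SE 0.35). Of 14 monooxygenases 2 rose, among them gh61-6 (2.83, SE 0.35), and 1 fell, the same numbers adjusted over the list alone (camera adjusted p = 0.67), or 3 and 2 with DESeq2. The cellulases had a median of -1.04 and a mean of -0.40, the monooxygenases a median of -0.20 and a mean of 0.23, and the test direction was higher for both. Of 12 genes of glycolysis and fermentation 5 fell (camera adjusted p = 0.000408, and adjusted p = 0.324 with an estimated correlation), of 33 aminoacyl-tRNA synthetases 9 fell (8.21e-05, and adjusted p = 0.331 with an estimated correlation), and of 14 heat shock genes 4 fell (0.00663, and adjusted p = 0.452 with an estimated correlation; 0.0574 without wild-type library 3). Of these lists 8, 11 and 5 genes fell when adjusted over the list alone, DESeq2 called 9, 14 and 5 lower, and limma called 1, 5 and 4. The alpha-glucosidase gene gh31-3 fell (-3.80, SE 0.42), the only edgeR call among 7 starch genes, of which DESeq2 called 2 lower (camera adjusted p = 0.0556, and 0.0465 without A828V library 3), and acu-5 fell (-3.31, SE 0.54; camera adjusted p = 0.575 for its list). In each of these lists 1 gene was lower adjusted over the list alone. Of 8 light and clock genes 2 rose, among them al-3 (2.26, SE 0.26; camera adjusted p = 0.0194, and adjusted p = 0.324 with an estimated correlation), and adjusted over the list alone 3 rose. The light and clock list did not pass without wild-type library 2 (0.0506) or 3 (0.0574). Of 29 proteasome genes 1 fell (camera adjusted p = 0.00762, and adjusted p = 0.678 with an estimated correlation), and 1 of 8 regulators, cre-1, fell (-2.39, SE 0.60; camera adjusted p = 0.67). Adjusted over the list alone 0 proteasome genes and 1 regulator were lower, and of the proteasome DESeq2 called 3 lower and limma 0. The cre-1 call was lost without wild-type library 3 (-2.19) or any 1 A828V library (-2.39, -2.54 and -2.25). edgeR called 0 of the 4 folding genes and of the 1 tested mating type A gene, with 0 at an unadjusted p under 0.05, by DESeq2 or by limma (camera adjusted p = 0.965 for folding). None passed when adjusted over the list alone. By fry the starch genes passed toward lower values (adjusted p = 0.00556), while proteasome (0.131) and heat shock genes (0.0776) did not pass. Of the engineered loci ccg-1 rose (1.98, SE 0.43) and his-3 fell (-1.57, SE 0.32), also adjusted over the list alone (camera adjusted p = 0.965), with a median of -0.20, a mean of 0.07 and a test direction of lower. The ccg-1 call was lost without A828V library 3 (1.89).

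NCU09968 and the overlapping gene NCU09969 had at most 2 reads each in any of the 4 A828V libraries, on both media, while the genes on both sides were read in each. A loss or change of the locus in the A828V strain is a candidate explanation, with the highest count of either gene at 2 in these libraries. Absence of a carbon source is argued against by the authors' deposited table, where NCU09968 had a log2 change of -0.081 between wild type on xylan and without carbon. Repression by the A828V protein cannot be told apart from a change in the strain, since strain and allele go together, and NCU09968 stood at -0.99 on the log2 scale in the deletion strain against wild type.

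The 1778 calls between A828V without carbon and wild type on xylan came from 1 of 10 splits of the 6 libraries, the highest other split gave 0, and 10 splits are too few for a share under 0.05.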
